A study of Oncorhynchus mykiss with 32 samples.

How the data were processed

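RNA from whole intestine of rainbow trout was sequenced as paired, stranded, poly(A)-selected libraries on an Illumina NextSeq, per the labels. The labels give 2 strains, a viral or mock challenge and 2 days, hence 8 groups with 6 infected or 2 sham pools each. A pool holds 2 fish, and 2 pools come from each tank, so the 32 libraries stand for 16 pairs of pools that share a tank. The strains were reared together from the egg before they were stocked in separate tanks, per the labels. Samples were grouped by the labels alone.

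The deposited files are 1 quantification table per library from Salmon 1.2.1, as the submitters' processing notes say. Per the file headers each table gives estimated counts, TPM, length and effective length for 78931 transcripts. The index and genome build are not given in the sources used here. Of the deposited estimated counts above 0, 41.1% were whole numbers. The others are fractions because Salmon divides reads among similar transcripts, and counts were rounded to whole numbers after summing per gene. The deposited TPM values were not used here. The deposited effective lengths served only as offsets in an alternative. Raw reads and viral reads were not analysed here.

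Transcripts were matched to genes by RefSeq accession without version number. This matched 42376 transcripts (53.7%) to 25115 genes, 6926 with a symbol and 18189 with a locus number only, against 1083 (1.4%) with the version number. The 36555 transcripts without a match were kept as features of their own, so 61670 features entered the filter. Matched transcripts held 62.5% to 66.9% of estimated reads (median 65.2%), and genes with a symbol 22.3% to 23.9%. The trout lineage has a duplicated genome, so a gene with near-identical copies may share its reads with a copy under another name. The top transcript held 0.58% to 2.91% of reads, the top 10 held 4.6% to 7.2%, and 42460 to 46909 transcripts were detected per library.

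Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust) and limma 3.58.1 in R 4.3.3, with 1 fit of all 32 libraries, 1 mean per group and 24 residual degrees of freedom. filterByExpr (minimum count 10, total 15, proportion 0.7) kept 36489 features, which hold 99.7% to 99.8% of reads. TMM factors ran from 0.874 to 1.12, and the biological coefficient of variation was 0.495. Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. Pools were treated as replicates, although pairs of them share a tank.

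The 12 comparisons were infected against sham in each strain and day, select against commercial in infected and in sham fish on each day, the difference of the responses on each day, and 20 against 4 dpc in infected fish of each strain. These comparisons, their tests, the gene lists and the rule for naming genes were set before the data were examined. Under that rule a named gene has an adjusted p below 0.05, a mean of at least 1 CPM in the higher group, no overlap between the groups in CPM and a known product. The 10 largest rises and 10 largest falls were named in infection and infected strain comparisons and 5 of each in the others, without the overlap condition for response differences. From each list with a called member up to 4 members of smallest p were named, and from a list that passed camera without one its first 2.

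Each of 23 lists of genes was tested where 3 or more members were measured (21 lists) with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the data was run beside it. Lists were interferon response, antigen presentation, inflammation, T and NK cells, B cells, myeloid cells, erythrocytes, exocrine pancreas, liver, enterocytes, goblet and enteroendocrine cells, smooth muscle, skeletal muscle, adipose tissue, proliferation, sterol synthesis, fatty acid oxidation, growth axis, ER and heat stress, complement, epithelial barrier, detoxification and oxidative stress, and extracellular matrix. List means of log2 CPM (prior count 2) were compared by exact two-sided permutation tests. CPM are given as mean ± SD over pools, and log2 fold changes with the SE of the fit. The floor is 3 counts per library, and a fold change against a group at 0 counts is a lower bound from that floor. Such floors cover counting error only and not variation between fish.

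The pipeline was tested on simulated data with 100 changed genes of 35245 at each of 2 and 4-fold. The changed genes were drawn from features with a mean of at least 2 CPM, so recovery nearer the floor was not tested. Differences between tanks and pools that stand apart were not simulated. At 2-fold 58% were recovered in the infected strain comparison of 4 dpc, 31% for infection in the select strain, 15% for the response difference at 4 dpc, 26% between sham strains, 16% for the response difference at 20 dpc and 57% between days. At 4-fold these were 78%, 69%, 57%, 60%, 46% and 80%. No recovered gene had the wrong sign, and 0 to 7 of 35023 or 35045 unchanged genes were called, or 1 of 35245 in a comparison without any simulated change. A simulated shift of 0.5 over 22 interferon genes gave a camera adjusted p of 0.00217, with 0 of 20 other lists called. Genes were simulated independently of each other, whereas the estimated correlation of interferon genes in the data was 0.689. The simulation therefore cannot show how often camera at the preset correlation calls correlated lists falsely.

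Alternatives set beforehand were RLE scaling, no expression filter, limma-voom with pools of a tank correlated, DESeq2 1.42.0 (Wald test), effective length offsets, pools summed by tank, a replicate block from the labels, a fit of the compared groups only, omission of each library in turn, an estimated correlation for camera and a prior count of 0.5. The block was the pool number in the fit of all libraries, the tank and pool number in a fit of the 12 infected libraries of a day for infected strains, and the tank in a fit of the 12 infected libraries of a strain for days. DESeq2 replaced its parametric dispersion trend by a local fit and tested 23036 to 35539 features after its own filter. Matched genes alone, older gene symbols in the lists, list tests with each library omitted and omission of the pools TI3-2 and CI3-2 of 4 dpc were added after the data were seen. Tables were joined in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9. Paired pools of a tank were checked for duplication: the lowest chi-square per degree of freedom was 8.08 between infected libraries of a group and 7.1 between sham libraries. Libraries of 1 tank correlated at a mean r of 0.885 to 0.902, others of the same group at 0.884 to 0.900.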

Results

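### RNA-seq of trout intestine in a select and a commercial strain after IHNV challenge

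Gene expression was measured by stranded, poly(A)-selected RNA-seq of whole intestine from all-female rainbow trout of 2 strains, named select and commercial in the labels. Fish met infectious hematopoietic necrosis virus (IHNV), a rhabdovirus of salmonids, by bath or received a mock (sham) challenge, and intestines were taken at 4 and 20 days post challenge (dpc). Each library is a pool of 2 fish, with 2 pools from each tank. On each day each strain gave 6 infected pools from 3 tanks and 2 sham pools from 1 tank, 32 libraries in all. With 1 sham tank per strain, an effect of that tank cannot be separated from the challenge in any infected against sham comparison. Libraries held 6.66 M to 11.33 M estimated reads (median 7.81 M). The floor of 3 counts lay at 0.265 to 0.45 CPM, the unit of counts scaled to library size. Tests covered 36489 features: 5484 genes with a symbol, 12528 genes known by a locus number alone, and 18477 transcripts without a match in the gene table. Principal component 1 held 14.9% of the variance and component 2 held 6.7%.

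**Figure D1:**
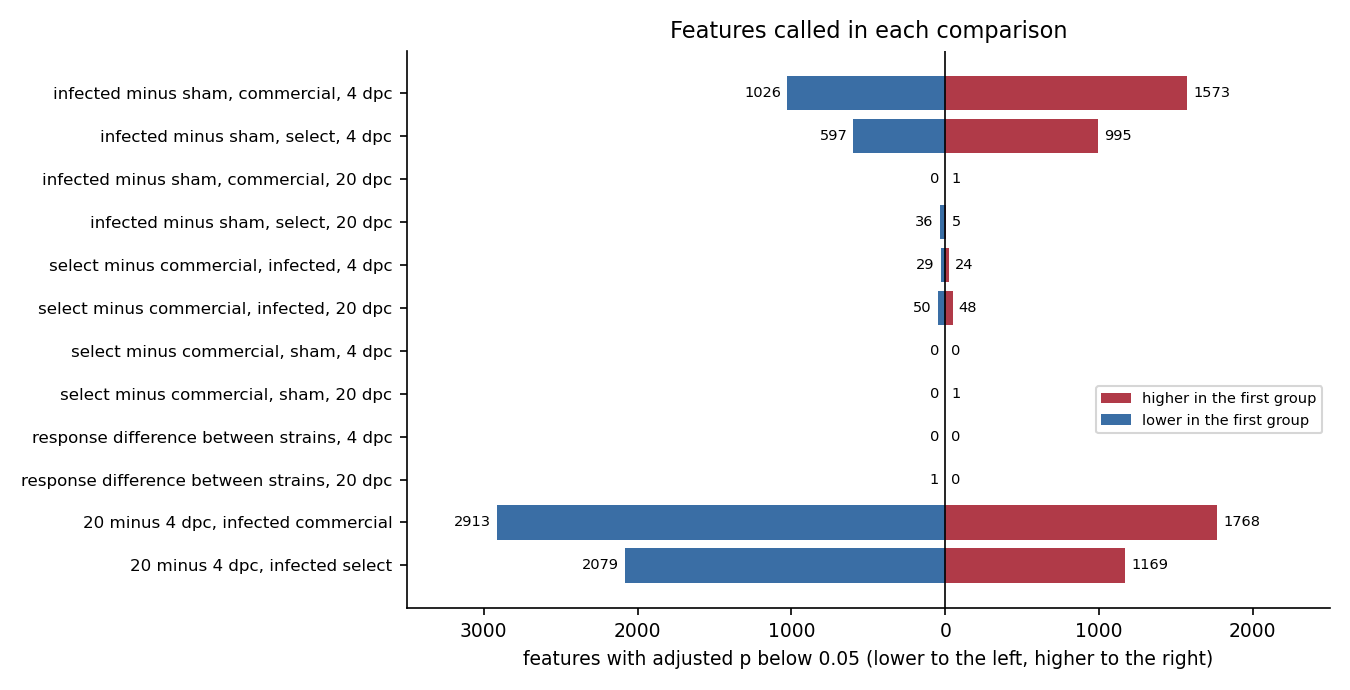
Features with an adjusted p below 0.05 in each of 12 comparisons, with lower features to the left and higher features to the right. The tallies at 4 dpc (1573 up and 1026 down in the commercial strain) stand against 1 and 41 features at 20 dpc.

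### Infection at 4 dpc raised interferon and antigen presentation genes in the commercial strain

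The first comparison asked what infection changed in commercial intestine at 4 dpc. The chemokine gene ccl19a.1, whose product attracts lymphocytes and dendritic cells, averaged 416 ± 222 CPM (SD, n = 6) in infected pools and 0.734 ± 0.521 (n = 2) in sham pools. Its log2 fold change was 9.11 ± 2.53 (SE; adjusted p = 0.0277, edgeR with Benjamini-Hochberg adjustment, as for all genes in this section). The antiviral GTPase gene mx rose by 6.04 ± 1.54 (adjusted p = 0.0174; 227 ± 95 against 3.43 ± 3.64 CPM), and mx2 rose by 5.47 (adjusted p = 0.0392). Rises of similar size were measured for batf2 (5.78, adjusted p = 0.024), vig-2 (5.64 ± 1.36, 0.0133), the chemokine gene cxcf1b (5.25), ifit8 (5.23 ± 1.19, 0.00995), the RNA sensor gene dhx58 (5.02 ± 1.41, 0.0294) and the nucleotide kinase gene cmpk2 (5 ± 1.5, 0.042). The feedback inhibitor gene socs1 rose by 5.37 ± 1.35 (adjusted p = 0.0162; 117 ± 71.1 against 2.81 ± 0.182 CPM).

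Of 22 measured members of the interferon list, 17 rose and 0 fell, or 20 rose when adjusted over the list alone, with a median log2 fold change of 2.96. Examples are irf9 (2.62 ± 0.49, adjusted p = 0.00354 by edgeR), ifi35 (2.33, 0.00416) and tlr3, a receptor for double-stranded RNA (1.88 ± 0.34, 0.00266; 195 ± 49 against 52.8 ± 19 CPM). The list passed camera (adjusted p = 6.31e-22, and adjusted p = 0.0726 with an estimated correlation). All 7 measured antigen presentation genes rose (camera adjusted p = 9.95e-11, 0.0401 with an estimated correlation). Among them were the immunoproteasome gene psmb8a (2.05 ± 0.33, adjusted p = 0.00124; 126 ± 31 against 30.5 ± 0.161 CPM), the peptide transporter gene tap1 (2.59 ± 0.50, 0.00399; 238 ± 94.7 against 39.4 ± 4.45 CPM), tapbp.1 (3.02 ± 0.61, 0.00498) and cd74b (0.96 ± 0.18, 0.00363).

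Of 9 inflammation genes 4 rose and 0 fell, or 6 rose when adjusted over the list alone, among them nfkbiab (1.33, adjusted p = 0.0159) and socs3 (2.97, 0.0401), both by edgeR. This list passed camera at adjusted p = 3.6e-05 (adjusted p = 0.11 with an estimated correlation). Of 11 T and NK cell genes 2 rose, or 4 when adjusted over the list alone: prf1, which encodes perforin (2.69 ± 0.47, adjusted p = 0.00235; 12.7 ± 2.5 against 1.95 ± 1.2 CPM), and tbx21 (2.29 ± 0.68, 0.0388). Camera gave 4.31e-05 for this list (0.0401 with an estimated correlation). Of 5 myeloid genes 0 passed alone and 3 did when adjusted over the list alone, with mpeg1.1 (0.77, adjusted p = 0.0534) and ncf1 (0.92, 0.0819) closest. Camera gave 0.0108 for them (adjusted p = 0.29 with an estimated correlation). Of 10 complement genes c7b rose (3.09 ± 0.75, adjusted p = 0.0137; 22.5 ± 14.3 against 2.63 ± 0.251 CPM), or 2 when adjusted over the list alone. Complement passed camera at 0.0148 (adjusted p = 0.194 with an estimated correlation) and did not without the sham pool TIControl-1 (0.111).

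Among genes that fell, the urea cycle gene cps1 averaged 0.0482 ± 0.0747 CPM in infected pools, under the floor, and 3.3 ± 0.184 in sham pools (log2 fold change −5.70 ± 0.87, adjusted p = 0.00092 by edgeR). Further falls were cks2 (−2.32 ± 0.54, 0.0108), tmem44 (−2.17), the retinol-binding gene rbp7b (−2.05 ± 0.45, 0.00792; 1.55 ± 0.575 against 6.48 ± 2.27 CPM), qpctlb (−2.04), the mitochondrial RNA-binding gene slirp (−2 ± 0.38, 0.00373), sobpa (−1.98), fam169ab (−1.89), the ketone body gene bdh1 (−1.75 ± 0.42, 0.0124; 3.33 ± 1.64 against 11.2 ± 2.38 CPM) and nmt2 (−1.67). Of 9 sterol synthesis genes 2 fell, or 4 when adjusted over the list alone, among them sc5d (−1.05 ± 0.27, 0.0176; 119 ± 29.6 against 246 ± 18.6 CPM). Camera stood at 0.00233 (adjusted p = 0.373 with an estimated correlation). Of 10 fatty acid oxidation genes 4 fell, or 6 when adjusted over the list alone: acaa2 (−0.90 ± 0.22, 0.0126; 91.1 ± 21.3 against 170 ± 16.9 CPM), acadvl (−0.78, 0.0225), pparab (−0.75, 0.0296) and pdk4 (−1 ± 0.26, 0.0178). For this list camera stood at 0.000823 (adjusted p = 0.194 with an estimated correlation).

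Of 5 detoxification and antioxidant genes 3 fell, also when adjusted over the list alone: gpx1 (−1.12 ± 0.23, adjusted p = 0.00563 by edgeR; 11.1 ± 2.55 against 24.2 ± 5.44 CPM), sod1 (−0.69, 0.0328) and gclc (−0.84, 0.0357). That list passed camera at 0.0108 (adjusted p = 0.11 with an estimated correlation) and did not without TIControl-1 (0.0917). None of 7 proliferation genes passed alone, with tpx2 at −0.68 (0.194) and birc5a at −0.78 (0.283), while the list was lower by camera (0.0297, or 0.394 with an estimated correlation). This call was lost without TI1-2 (0.0596), TI2-1 (0.0651), TI3-2 (0.0833) or TIControl-1 (0.154). In the growth axis list igfbp6 rose (1.27, 0.0477) and the list did not pass (0.776). Camera called no other list: B cell 0.337, liver 0.621, enterocyte 0.511, goblet and enteroendocrine 0.84, smooth muscle 0.616, skeletal muscle 0.268, adipose 0.511, ER and heat stress 0.962, epithelial barrier 0.511, extracellular matrix 0.896. Erythrocyte and exocrine pancreas had 1 measured member each and were not tested.

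In all, edgeR called 2599 features at adjusted p below 0.05, of which 1573 rose and 1026 fell. No overlap between infected and sham pools was seen in 2470 of them and in 21.5% of all tested features, where chance gives 7.14%. Called features are selected for separation, so their lack of overlap is no further evidence, here and in the other comparisons. Of those that rose 1171 (74.4%) changed more than 2-fold, against 306 (29.8%) of those that fell. The tally rests on the pair of sham pools: 88 features were called without TIControl-1 and 75 without TIControl-2. Of 43 called genes under the naming rule 41 lost their call without TIControl-1 and 41 without TIControl-2: mx stood at adjusted p = 0.134 and 0.246 (edgeR), psmb8a at 0.0544 and 0.0568. cps1 kept its call without TIControl-1 (0.0195) and without TIControl-2 (0.0093), tlr3 without TIControl-1 (0.0375, against 0.119) and prf1 without TIControl-2 (0.025, against 0.102). Without TIControl-1 the log2 changes of ccl19a.1 (10.09), mx (8.02), batf2 (7.82), cxcf1b (6.72), mx2 (6.43), dhx58 (5.99) and cmpk2 (5.92) were larger. Without TIControl-2 those of mx (5.24), batf2 (4.97) and cxcf1b (4.54) were smaller and that of prf1 (3.51) larger, and cks2 stood at −2.96 without TI2-2. Single infected pools ended at most 9 of the 43 calls, those of mx2, cmpk2, igfbp6 and gclc most often. It was 4386 by DESeq2, 971 with pools summed by tank and 618 with a fit of the compared groups only. The balance turned with limma-voom (1147 up and 1244 down).

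### Infection at 4 dpc raised interferon and antigen presentation genes in the select strain

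In select intestine at 4 dpc, mx rose by 7.76 ± 1.73 (adjusted p = 0.0123 by edgeR; 252 ± 93.1 CPM, SD, n = 6, against 1.14 ± 0.702, n = 2) and ifit9 by 7.56 ± 1.91 (0.0238; 716 ± 317 against 3.79 ± 2.32 CPM). The interferon signalling gene stat1b rose by 6.22 ± 1.37 (adjusted p = 0.0116; 206 ± 85.1 against 2.74 ± 0.0413 CPM). Next came mx2 (6.95, 0.0292), cmpk2 (6.42, 0.0257), ifit8 (6.03, 0.00937), vig-2 (5.95, 0.0158) and batf2 (5.57, 0.0434). Both sham pools held 0 counts of acod1, the gene of the itaconate-forming enzyme (at least 3.99-fold, adjusted p = 0.0451; 1.53 ± 0.615 CPM infected), and of faslg, the Fas ligand gene (at least 3.03-fold, 0.0234; 1.16 ± 1 CPM infected).

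Of 22 interferon genes 19 rose and 0 fell, or 20 rose when adjusted over the list alone (median 3.30, camera adjusted p = 7.93e-31, 0.0429 with an estimated correlation). Examples are tlr3 (2.34 ± 0.35, adjusted p = 0.0013 by edgeR; 216 ± 47.5 against 42.5 ± 0.398 CPM), irf3 (3.43 ± 0.60, 0.0034) and ifi35 (2.58). All 7 antigen presentation genes rose (camera 2e-10, 0.0429 with an estimated correlation), including psmb8a (1.97 ± 0.32, 0.00255; 146 ± 38.6 against 37.3 ± 3.76 CPM), tapbp.1 (2.81, 0.0101), tap1 (2.22 ± 0.49, 0.0111) and the MHC class I regulator gene nlrc5 (2.94 ± 0.66, 0.0131).

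Of 9 inflammation genes 2 rose, or 7 when adjusted over the list alone, one of them the gelatinase gene mmp9 (4.34 ± 1.21, adjusted p = 0.0399 by edgeR; 22.3 ± 14.7 against 1.09 ± 0.471 CPM). Camera gave 2.5e-05 for this list (adjusted p = 0.0957 with an estimated correlation). Of 11 T and NK cell genes 2 rose, or 4 when adjusted over the list alone, with prf1 at 2.09 ± 0.45 (0.0107; 11.5 ± 4.2 against 2.69 ± 0.951 CPM). For these camera gave 0.000242 (adjusted p = 0.0566 with an estimated correlation). Of 5 myeloid genes mpeg1.1, a perforin-like gene of macrophages, rose (1.00 ± 0.25, 0.0213; 69 ± 7.83 against 34.5 ± 3.08 CPM), or 2 when adjusted over the list alone. Here camera gave 0.00803 (adjusted p = 0.267 with an estimated correlation). Of 10 complement genes c7b rose (3.03 ± 0.74, 0.0201; 24.6 ± 16.7 against 2.99 ± 0.759 CPM), or 3 when adjusted over the list alone. Complement genes stood at 0.00592 by camera (adjusted p = 0.133 with an estimated correlation). Without the sham pool CIControl-1 neither the myeloid (0.123) nor the complement list (0.0962) passed.

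Falling genes again included cps1 (−2.64 ± 0.78, adjusted p = 0.0499 by edgeR; 0.402 ± 0.31 against 2.61 ± 0.766 CPM), tmem44 (−2.18) and rbp7b (−1.71, 0.0296). The transcriptional repressor gene bcl6b fell by 1.72 ± 0.41 (0.0169; 5.13 ± 2.2 against 17 ± 2.47 CPM) and the kinetochore gene knstrn by 1.60 ± 0.36 (0.0124; 3.75 ± 0.845 against 11.4 ± 1.38 CPM), next to gpx7 (−1.75, 0.0189), kpna7 (−1.66), akt3a (−1.52, 0.0083), rcn3 (−1.48, 0.0131) and agbl2. Of 7 proliferation genes the topoisomerase gene top2a fell (−0.92 ± 0.25, 0.0374; 64.3 ± 14.8 against 121 ± 16.2 CPM), or 5 when adjusted over the list alone. Camera gave 0.000347 (adjusted p = 0.155 with an estimated correlation). Of 10 fatty acid oxidation genes 3 fell, or 7 when adjusted over the list alone: pdk4 (−1.37 ± 0.25, 0.0039; 6.28 ± 1.82 against 16.3 ± 5.12 CPM), acaa2 (−0.85, 0.0235) and acadvl (−0.73, 0.0459). Their camera p was 2.5e-05 (adjusted p = 0.0957 with an estimated correlation). Of 9 sterol genes 1 fell, or 2 when adjusted over the list alone. Camera gave 0.0251 (adjusted p = 0.605 with an estimated correlation). The sterol call was lost without CI1-1 (0.0644), CI2-1 (0.051), CI3-1 (0.105) or CIControl-1 (0.104).

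Outside these lists, fabp2, which binds fatty acids in enterocytes, fell by 0.88 ± 0.25 (adjusted p = 0.0469 by edgeR; 2200 ± 696 against 4030 ± 1720 CPM). The heat shock gene hsp70b rose by 2.49 ± 0.63 (0.0242; 25.4 ± 16.2 against 4.49 ± 2.61 CPM), and sod1 (−0.86 ± 0.20, 0.0138) and gclc (−0.87, 0.0409) fell. Camera called neither enterocyte (0.174), ER and heat stress (0.263) nor detoxification genes (0.106), and the lists that did not pass spanned 0.106 to 0.969. edgeR called 1592 features, 995 up and 597 down, and 1514 had no overlap between groups (14.4% over all tested features, chance 7.14%). More than 2-fold changes made up 749 of those that rose and 218 of those that fell. Without CIControl-1 63 features were called and without CIControl-2 148. Of 41 called genes under the naming rule 39 lost their call without CIControl-1 and 37 without CIControl-2: mx stood at adjusted p = 0.183 and 0.131 (edgeR). tlr3 kept its call without each pool (0.0459 and 0.0334), and psmb8a without CIControl-2 (0.0424, against 0.0732). Log2 changes without CIControl-1 were 8.39 for ifit9, 7.71 for mx2, 6.83 for ifit8 and 3.26 for hsp70b, and without CIControl-2 8.57 for mx, 6.32 for batf2 and −1.21 for tmem44. Single infected pools ended at most 11 of the 41 calls, those of acod1 and kpna7 most often. DESeq2 called 3155, the test without an expression filter 1027, tank sums 392 and a fit of the compared groups only 176, and with limma-voom the balance turned (570 up and 727 down).

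### The strains shared much of the 4 dpc response, and edgeR called no difference in response

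The strains shared 728 features that rose, where 42.9 would be shared by chance (odds ratio 112, log10 p = −832, one-sided exact hypergeometric test), and 317 that fell, where 16.8 would be (odds ratio 56.2, log10 p = −340). The test treats features as independent, which they are not, so its p overstates the evidence. The shared rises were 73.2% of the rises of the select strain and 46.3% of those of the commercial strain, and the shared falls 53.1% and 30.9%. No feature was called in opposite directions, and 3075 of 3146 features called in either strain (97.7%) had the same sign in both. The tally of 1045 shared features fell to 42 without TIControl-1, 44 without TIControl-2, 34 without CIControl-1 and 92 without CIControl-2. It was 2058 by DESeq2, 682 without an expression filter, 265 with tank sums and 112 with fits of the compared groups only.

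Mean log2 CPM over the interferon list was 7.22 ± 0.61 in infected commercial pools and 7.15 ± 0.68 in infected select pools at 4 dpc (SD, n = 6 each; exact two-sided permutation p = 0.766, adjusted p = 1). Tested as a difference between the responses of the strains at 4 dpc, edgeR called 0 features (smallest adjusted p = 1, 1189 features at unadjusted p below 0.05), limma-voom 0, DESeq2 52 and tank sums 2. Leaving out a sham pool gave 9 calls (TIControl-1), 15 (TIControl-2), 7 (CIControl-1) and 3 (CIControl-2). No list passed (adjusted p 0.323 to 0.89), and the interferon list stood at 0.323, with a median difference of 0.50 and 19 of 22 genes of larger response in the select strain (unadjusted p = 0.0365). On simulated data 15% of 2-fold response differences were recovered, so a lack of calls does not show equal responses. The sham pool TIControl-1 of 4 dpc also stood above the other sham pools of that day, with an interferon list mean of 4.49 (others 3.38 to 3.64) and 27.6 CPM of ifit9 (others 2.14 to 5.43). In the interferon list ifit9 passed in the select strain and not in the commercial strain (5.20, adjusted p = 0.057 by edgeR), which does not show a difference between strains. helz2a passed in neither (4.74, 0.056 commercial, and 5.31, 0.051 select).

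**Figure D2:**
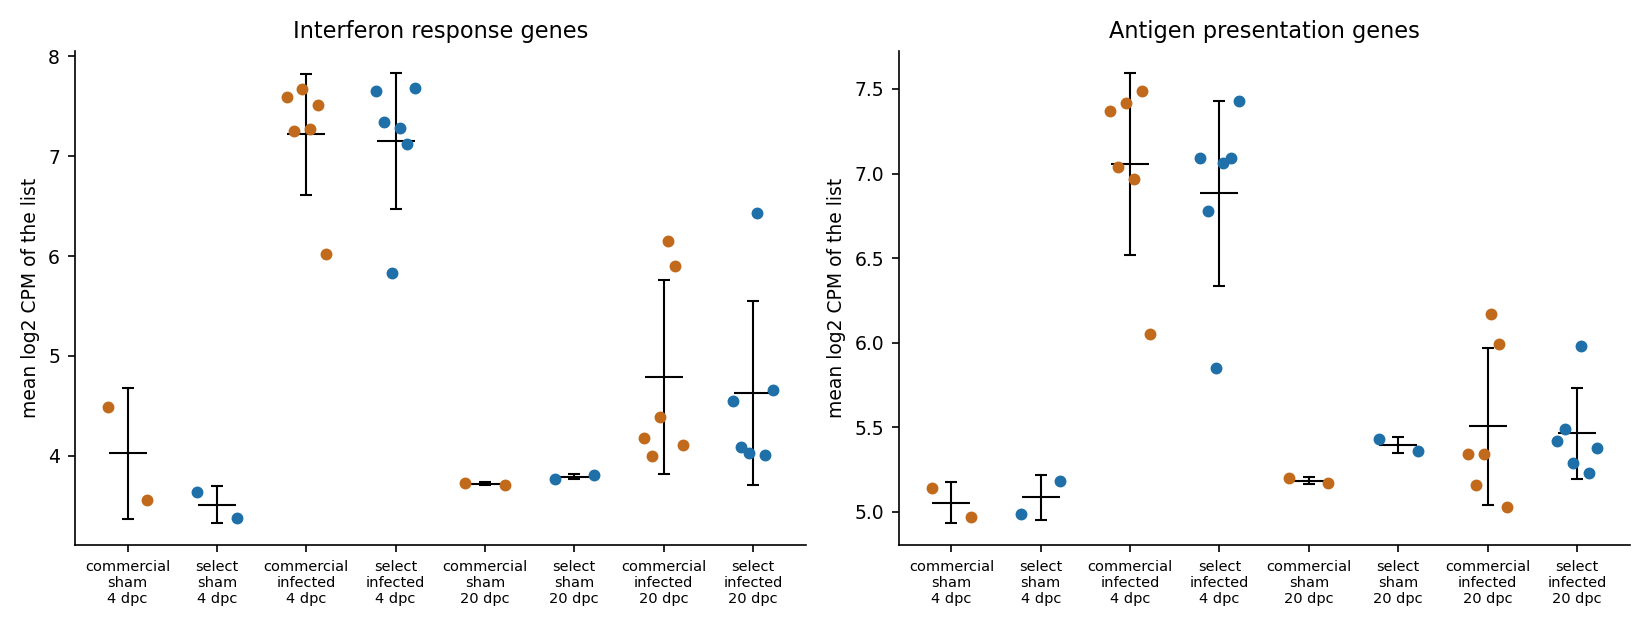
Mean log2 CPM of the interferon and antigen presentation lists in each library, with group mean and SD. Infected pools at 4 dpc lie above sham pools in both strains (interferon 7.22 commercial, 7.15 select), and at 20 dpc the infected means were 4.79 and 4.63.

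### At 20 dpc single genes rarely passed, while interferon and sterol lists were higher

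By 20 dpc no gene with a symbol passed in the commercial strain. The interferon gene ifit9 stood at 5.61 ± 1.82 (adjusted p = 0.393 by edgeR; 61.3 ± 84.1 CPM, SD, n = 6, against 1.26 ± 0.744, n = 2) and stat1b at 3.27 (0.438). ifit9 stood at 4.6 without TI2-2 and 6.35 without TIControl-1. As a list, the 22 interferon genes were higher (median 1.10, camera adjusted p = 1.71e-06, and adjusted p = 0.47 with an estimated correlation) with 0 passing alone or when adjusted over the list alone. The pools TI2-2 and TI3-1 carried most of it, with list means of 6.15 and 5.9 (others 4 to 4.39) and 83.9 and 47.9 CPM of mx (others 4.08 to 13.1). Sterol genes were higher (0.00969, or 0.476 with an estimated correlation), led by fdps (1.11, adjusted p = 0.54; 24.6 ± 8.05 against 11.3 ± 5.76 CPM) and idi1 (0.98, 0.632), but not without TIControl-1 (0.2). Enterocyte genes were higher (0.00969, or 0.47 with an estimated correlation), with anpepb (0.40, 0.496) and vil1 (0.34, 0.497) first, but not without TIControl-2 (0.0697).

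Collagen and muscle genes were lower in infected commercial pools at 20 dpc. The extracellular matrix list passed camera at 1.13e-05 (adjusted p = 0.297 with an estimated correlation), with col5a2a at −0.98 ± 0.19 (adjusted p = 0.196 by edgeR; 82.3 ± 12.4 against 162 ± 50.3 CPM) and col1a1b at −0.86 (0.364). Adjusted over the list alone, 4 members fell. Smooth muscle genes followed (0.000549, or 0.297 with an estimated correlation), with smtnb at −0.65 (0.43) and smtna at −0.74, 4 of them lower when adjusted over the list alone. The growth axis list was lower (0.0109, or 0.297 with an estimated correlation), with igf1, the insulin-like growth factor gene, at −1.08 (0.511; 6.36 ± 2.05 against 13.5 ± 2.16 CPM) and igfbp2 at −0.90 (0.495). Neither smooth muscle (0.2) nor growth axis (0.244) passed without TIControl-1. edgeR called 1 feature, LOC110507825, higher in infected pools (at least 33.2-fold over 0 counts, adjusted p = 5.8e-09, 3104 features at unadjusted p below 0.05). It had no overlap between groups (12% over all tested features, chance 7.14%). The tally was 3 without TI1-2, 2 without TI2-2, 3 without TI3-1, 7 without TIControl-1 and 19 without TIControl-2. DESeq2 called 254, limma-voom 54, tank sums 4, matched genes alone 3 and a fit of the compared groups only 2.

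In the select strain at 20 dpc the alpha globin gene hba1 fell by 1.66 ± 0.31 (adjusted p = 0.0333 by edgeR; 16 ± 3.57 CPM, SD, n = 6, against 50.6 ± 0.0788, n = 2). Falls were also called for gbp (−2.22 ± 0.45, 0.0406; 8.25 ± 3.87 against 38.6 ± 3.7 CPM), the peptidase inhibitor gene pi15b (−2.31 ± 0.47, 0.0395; 1.04 ± 0.296 against 5.25 ± 0.36 CPM), the RNA helicase gene mov10a (−1.44 ± 0.30, 0.0462) and spen (−0.97 ± 0.19, 0.0368; 12.8 ± 1.24 against 25.1 ± 2.09 CPM). The mitochondrial ribosome gene mrpl19 rose by 1.07 ± 0.20 (0.0333; 14.6 ± 1.06 against 6.95 ± 0.727 CPM). All 6 calls were lost without CI3-1, CI3-2, CIControl-1 or CIControl-2 (hba1 at 0.0678, 0.0587, 0.291 and 0.308), 5 without CI1-1, and 4 without CI2-1 or CI2-2. Over all alternatives adjusted p of hba1 ran from 0.000257 to 0.308. At 4 dpc select sham pools averaged 23.4 ± 0.328 CPM of hba1 and 19.4 ± 4.26 of gbp, and infected pools 19.5 ± 6.28 and 6.67 ± 3.17. The falls of these genes at 20 dpc thus coincide in part with a day difference in the sham pools. In the commercial strain at 20 dpc hba1 was at 14.6 ± 4.8 against 33.6 ± 6.58 CPM and did not pass (0.328).

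Among select lists at 20 dpc, sterol genes were higher (camera adjusted p = 0.00169, and adjusted p = 0.618 with an estimated correlation), 4 of them when adjusted over the list alone, led by mvda (1.67, 0.148 by edgeR) and fdft1 (1.29, 0.179; 87.7 ± 8.2 against 35.9 ± 0.725 CPM), both of cholesterol synthesis. Interferon genes were higher (0.00246, or 0.976 with an estimated correlation; median 0.65), with stat1b at 3.45 (0.196) and ifit9 at 4.64 (0.203), but not without CI2-2 (0.108). That pool held 376 CPM of ifit9, against 11.3 to 40.4 CPM in the other 5, and without it ifit9 stood at 2.73 and stat1b at 2.43. ER and heat stress genes were higher (0.0199, or 0.618 with an estimated correlation), with creld2 at 0.90 (0.145) and canx at 0.59 (0.174), 2 when adjusted over the list alone, but not without CIControl-1 (0.128). Myeloid genes were higher (0.0479, or 0.618 with an estimated correlation), with ncf4 at 1.81 (0.145) and csf3r at 1.15 (0.254), 2 when adjusted over the list alone. The myeloid call was lost without CI1-1 (0.13), CI1-2 (0.0635), CI3-1 (0.0818), CI3-2 (0.112), CIControl-1 (0.0751) or CIControl-2 (0.172).

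edgeR called 41 features in the select strain at 20 dpc, 5 up and 36 down, all 41 without overlap between groups (19.8% over all tested features, chance 7.14%). The tally was 10 without CI1-1, 87 without CI1-2, 16 without CI2-1, 8 without CI3-1, 10 without CI3-2, 13 without CIControl-1 and 13 without CIControl-2. DESeq2 called 1218, limma-voom 189, a fit of the compared groups only 89, the test without an expression filter 11 and tank sums 5. The balance of up and down calls turned with the method: 768 up and 450 down by DESeq2, 59 and 30 with the compared groups only, 3 and 2 with tank sums, 9 and 4 without CIControl-1 and 10 and 3 without CIControl-2.

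**Figure D3:**
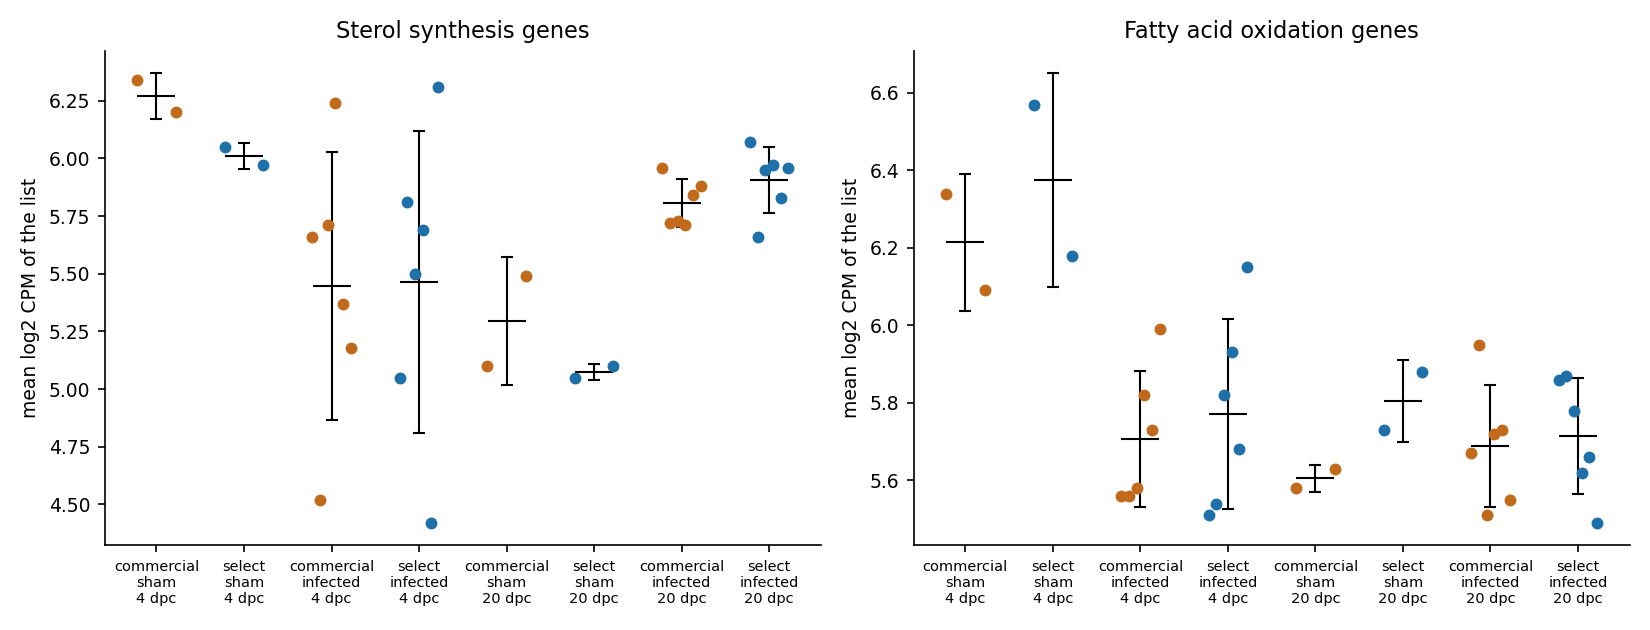
Mean log2 CPM of the sterol synthesis and fatty acid oxidation lists in each library, with group mean and SD. Sterol means of sham pools were 6.27 and 6.01 at 4 dpc and 5.3 and 5.08 at 20 dpc (commercial, then select).

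### From 4 to 20 dpc the interferon response fell in infected fish of both strains

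Infected pools of 20 dpc were compared with those of 4 dpc in each strain (n = 6 each). In the commercial strain ccl19a.1 fell by 4.26 ± 1.13 (adjusted p = 0.0131 by edgeR; 21.7 ± 33.2 against 416 ± 222 CPM, SD), tap1 by 1.90 ± 0.31 (0.000243; 63.7 ± 24.1 against 238 ± 94.7 CPM) and the interferon gamma gene ifng by 3.91 ± 1.12 (0.0227; 0.157 ± 0.228 against 2.57 ± 1.47 CPM). The largest falls among genes without overlap were plch2a (−4.89 ± 1.09, 0.00348), the hormone gene fgf21 (−3.47 ± 1.07, 0.0315; 0.207 ± 0.102 against 2.47 ± 1.74 CPM), gig2p (−2.64), bcl3 (−2.57, 0.000391) and faslg (−2.57, 0.0182). The largest rises were cyp1a3, a cytochrome P450 of the response to xenobiotics (2.74 ± 0.50, 0.000723; 451 ± 183 against 67.4 ± 39.4 CPM), nsd1b (2.13), b4galnt4a (1.90), pkd1l2a (1.65) and qpctlb (1.64). The growth factor gene igf1 rose by 1.47 ± 0.35 (0.00543; 6.36 ± 2.05 against 2.29 ± 0.665 CPM), and irs1 by 0.95.

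Of 22 interferon genes 19 fell and 0 rose in the commercial strain, or 20 fell when adjusted over the list alone (median −2.31, camera adjusted p = 4.03e-20, and adjusted p = 0.143 with an estimated correlation). All 7 antigen presentation genes fell (camera 7.61e-10, or 0.107 with an estimated correlation), with psmb9a at −1.77 (adjusted p = 0.000157 by edgeR), psmb8a at −1.26 and tapbp.1 at −2.09. Of 9 inflammation genes 4 fell, or 5 when adjusted over the list alone (0.00104, or 0.385 with an estimated correlation), socs1 by 3.59 ± 0.73 (0.00169). Of 7 proliferation genes mcm7 (−0.44, 0.0119) and top2a (−0.65, 0.0227) fell, or 4 when adjusted over the list alone. Camera gave 0.0398 (adjusted p = 0.518 with an estimated correlation). That call was lost without TI2-1 (0.0533) or TI2-2 (0.0577) of 20 dpc and without TI1-1 (0.0663) or TI2-2 (0.166) of 4 dpc. Of the lists that did not pass camera, 3 T and NK cell genes fell (0.0805), among them prf1 (−1.71 ± 0.28, 0.000306), and 3 complement genes fell (0.0805): c7b (−1.93), cfh (−1.98) and c9 (−1.93).

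Of metabolic genes in the commercial strain, lpl (1.33, adjusted p = 0.0256 by edgeR), fabp2 (0.61, 0.0306), pparab (0.56, 0.0166), gclc (0.69, 0.012) and gpx1 (0.57, 0.0312) rose, and the fatty acid oxidation gene cpt1ab fell (−1.11, 0.00679). The heat shock genes hsp70b (−1.47, 0.0105) and hsp70a (−1.13) fell, serpinh1a rose (0.72), and cdx1 (−0.63) and cldn15lb (−0.55) fell. edgeR called 4681 features, 1768 up and 2913 down, and 1666 had no overlap between days (5.1% over all tested features, chance 0.216%). Tank sums called 2666. Of 42 called genes under the naming rule single omissions ended at most 7 calls, most often those of fgf21, serpinh1a and cldn15lb. The pool TI2-1 of 20 dpc held the reads of plch2a (−9.70 without it) and moved cfh (−2.61), and without TI2-2 of 20 dpc ccl19a.1 stood at −5.51 and ifng at −4.89.

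In the select strain tlr3 fell by 1.61 ± 0.22 (adjusted p = 7.93e-05 by edgeR; 70.6 ± 20 against 216 ± 47.5 CPM, SD, n = 6 each) and eif2ak2, the gene of the RNA-activated kinase PKR, by 2.15 ± 0.33 (0.000279; 17.7 ± 6.51 against 78.5 ± 35.7 CPM). Of 22 interferon genes 18 fell and isg20 rose (0.73, 0.022), or 20 fell and 1 rose when adjusted over the list alone (median −2.42, camera 6.88e-24, and adjusted p = 0.0816 with an estimated correlation), irf9 by 1.84. All 7 antigen presentation genes fell (5.95e-10, or 0.0816 with an estimated correlation), nlrc5 by 2.29 (0.000793), tapbp.1 by 2.19, tap1 by 1.80 and psmb8a by 1.21. Of 9 inflammation genes 4 fell (0.00252, or 0.489 with an estimated correlation), among them socs1 (−2.94, 0.00961) and ccl19a.1 (−3.62, 0.0389; 20.4 ± 33.5 against 250 ± 181 CPM).

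The repressor gene bcl6b rose by 1.54 ± 0.32 in the select strain (adjusted p = 0.00322 by edgeR; 14.9 ± 2 against 5.13 ± 2.2 CPM), next to sacs (2.30 ± 0.63, 0.0218), tex9 (1.67), tnfaip6 (1.59, 0.037), fkbp1ab (1.59, 0.00757) and serpinh1a (0.80). Falls were called for cblnl (−2.91), faslg (−2.71, 0.0214), prf1 (−0.89, 0.042), the muscle gene myl1 (−3.34, 0.0468), c7b (−1.81), hsp70a (−1.20, 0.0143) and cpt1ab (−1.06, 0.013). fabp2 (0.62, 0.0395) and gclc (0.66, 0.0213) rose as in the commercial strain. edgeR called 3248 features, 1169 up and 2079 down, and 838 had no overlap between days (2.8% over all tested features, chance 0.216%). The tally was 2163 without CI3-1 of 20 dpc, 1334 with tank sums, 1398 with a fit of the compared groups only and 556 with a replicate block for the tank, fitted to the infected select libraries alone. Of 28 called genes under the naming rule single omissions ended at most 9 calls, most often those of tex9, serpinh1a and ccl19a.1. Without CI2-2 of 20 dpc ccl19a.1 stood at −5.18 and socs1 at −3.85, and myl1 at −4.57 without CI1-1 of 20 dpc and −1.85 without CI1-1 of 4 dpc. These comparisons use the same 4 dpc libraries as the infection comparisons, so their reversed signs are not independent findings, and day differs with fish age. The interferon list mean was lower at 20 than at 4 dpc in both strains (exact two-sided permutation p = 0.00433 over 924 arrangements in each, adjusted p = 0.0303 commercial and 0.0455 select), as was that of antigen presentation genes (same p). By this test T and NK cell (−0.59, adjusted p = 0.0303), inflammation (−1.69, 0.0378) and epithelial barrier genes (−0.33, 0.0378) were lower and detoxification genes higher (0.26, 0.0341) at 20 dpc in the commercial strain. In the select strain T and NK cell (0.0756) and inflammation genes (0.0798) did not pass, nor did other lists in either strain (complement 0.0519 and proliferation 0.0908 in the commercial strain).

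### A small set of genes differed between infected fish of the strains

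Infected select pools were compared with infected commercial pools on each day (n = 6 each). At 4 dpc the phosphatase gene mdp1 was higher in the select strain by 2.55 ± 0.52 (adjusted p = 0.0438 by edgeR; 7.48 ± 0.713 against 1.26 ± 1.41 CPM, SD), as was grpel2, a mitochondrial co-chaperone gene (1.23 ± 0.22, 0.0211; 10.3 ± 2.48 against 4.36 ± 1.61 CPM). The call of mdp1 was lost in 9 of 12 omissions of 1 library and kept without TI3-1 (adjusted p = 0.0473 by edgeR), TI3-2 (0.00378, log2 3.17) or CI3-2 (0.0369), and that of grpel2 was lost without TI1-1 (0.0599), TI2-1 (0.0525) or CI2-2 (0.0526). edgeR called 53 features, 24 higher and 29 lower in the select strain, and 23 had no overlap between strains (0.4% over all tested features, chance 0.216%). No list passed camera (adjusted p 0.438 to 0.992). The tally was 13 without TI1-1, 16 without TI1-2, 11 without TI2-1, 25 without TI2-2, 23 without TI3-1, 208 without TI3-2, 22 without CI1-1, 22 without CI1-2, 23 without CI2-1, 11 without CI2-2 and 113 without CI3-2. It was 454 without both TI3-2 and CI3-2, an alternative chosen after the data were seen, and all 53 were among them. DESeq2 called 368 and the test without an expression filter 21. Tank sums, a fit of the compared groups only and a block for the replicate number called 0 each (3265, 1694 and 1202 features at unadjusted p below 0.05).

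At 20 dpc dhrs7, a short-chain dehydrogenase gene, had 0 counts in all 6 infected commercial pools and averaged 14 ± 5.29 CPM in infected select pools (at least 39.8-fold, adjusted p = 0.0381 by edgeR). Likewise casp had 0 counts in infected commercial pools (at least 5.05-fold, 0.0115, with 1.77 ± 1.34 CPM in select pools). Commercial sham pools of both days also had 0 counts of both genes. In select sham pools dhrs7 averaged 14.7 ± 1.64 CPM at 20 dpc and 14 ± 1.96 at 4 dpc (n = 2 each), so its difference is not particular to infected fish. Whether reads of these genes lie on another transcript was not tested. Higher in the select strain were tdrd9, a helicase gene of germ cells (3.65 ± 0.67, 0.013; 2.87 ± 1.49 against 0.215 ± 0.164 CPM), grpel2 (1.08 ± 0.22, 0.0281; 8.58 ± 2.92 against 4.05 ± 0.594 CPM), nipsnap3a (0.87 ± 0.18, 0.0329; 52.7 ± 7.93 against 28.8 ± 3.84 CPM), slc6a7 (0.76, 0.0142), d2hgdh (0.70 ± 0.14, 0.0238) and the peroxisomal protease gene lonp2 (0.60 ± 0.11, 0.0142; 96.9 ± 10.4 against 64.1 ± 6.98 CPM). Lower were sox11b (−2.37 ± 0.48, 0.0217; 0.786 ± 0.278 against 4.16 ± 2.31 CPM) and enpp6 (−0.73 ± 0.16, 0.0335; 99.6 ± 26.7 against 165 ± 9.05 CPM). The call of dhrs7 was lost in 11 of 12 omissions of 1 library (adjusted p 0.0592 to 0.0795) and kept without CI1-2 (0.0379). Over all alternatives each of the 10 genes lost its call at least once, with adjusted p up to 0.267 for dhrs7, 0.249 for lonp2, 0.183 for grpel2, 0.159 for tdrd9, 0.137 for slc6a7, 0.134 for enpp6, 0.132 for d2hgdh, 0.126 for nipsnap3a and for sox11b, and 0.118 for casp. Of 21 alternatives dhrs7 lost its call in 15, nipsnap3a in 12 and enpp6 in 11.

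Proliferation genes were higher in infected select pools at 20 dpc by camera (adjusted p = 0.0183, and adjusted p = 0.459 with an estimated correlation), with tyms at 0.62 (0.0797 by edgeR) and top2a at 0.36 (0.524), 1 of them when adjusted over the list alone, but not without CI1-1 (0.056). Complement genes were higher (0.021, or 0.459 with an estimated correlation), with cfh at 2.06 (0.0991) and c6 at 1.12 (0.376), 1 when adjusted over the list alone, but not without TI1-1 (0.0713), CI1-1 (0.056) or CI3-2 (0.0855). The interferon list means were 4.79 ± 0.97 in commercial and 4.63 ± 0.92 in select pools (SD, n = 6 each; exact two-sided p = 0.894, adjusted p = 0.97). By the same exact tests no list mean passed: liver 2.2 ± 0.29 in commercial and 1.69 ± 0.29 in select pools (p = 0.013, adjusted p = 0.16), skeletal muscle 1.81 ± 0.62 and 0.91 ± 0.39 (p = 0.0152, adjusted p = 0.16), complement 2.68 ± 0.43 and 3.32 ± 0.43 (adjusted p = 0.242) and proliferation 4.13 ± 0.15 and 4.45 ± 0.37 (adjusted p = 0.309).

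edgeR called 98 features between the infected strains at 20 dpc, 48 higher and 50 lower in the select strain, 75 without overlap (1.4% over all tested features, chance 0.216%). The tally was 65 without TI3-2, 56 without CI1-1, 173 without CI1-2, 59 without CI2-1 and 64 without CI3-1, and 591 by DESeq2, 12 with a block for the replicate number and 6 with tank sums. The days, sampled from the same tanks, shared 6 features higher in the select strain (0.0316 by chance, two-sided Fisher exact p = 4.95e-13) and 7 lower (0.0397, p = 8.92e-15). The test treats features as independent, which they are not. Of 138 features called on either day, 135 (97.8%) had the same sign on both. Of the 138, 127 also had that sign in sham fish on both days.

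Between sham fish of the strains (n = 2 each), edgeR called 0 features at 4 dpc (smallest adjusted p = 0.0971, 1613 at unadjusted p below 0.05; DESeq2 98, limma-voom 5, tank sums 3, matched genes alone 1) and no list passed (0.328 to 0.979). Leaving out TIControl-1, TIControl-2, CIControl-1 or CIControl-2 gave 8, 15, 15 and 11 calls. At 20 dpc the 1 called feature was LOC110507825, higher in the select strain (at least 39.8-fold over 0 counts, adjusted p = 7.4e-09). It had no overlap, as had 43.9% of all tested features, where chance gives 33.3%. The same omissions gave 7, 13, 7 and 9 calls, and DESeq2 250, tank sums 7, limma-voom 5, effective length offsets 3 and a fit of the compared groups only 0. Collagen and muscle genes were lower in select sham fish as lists. Extracellular matrix genes passed (camera 0.00965, or 0.724 with an estimated correlation), with sparc at −0.85 (0.533; 377 ± 33.7 against 678 ± 271 CPM) and col5a2a at −0.64 (0.466). Smooth muscle genes stood at the same p (0.00965, or 0.724 with an estimated correlation), with smtnb at −0.81 (0.415; 129 ± 32.4 against 226 ± 71.4 CPM) and lmod1b at −0.91 (0.413). Adjusted over the list alone 4 and 2 members were lower. Matrix genes did not pass without TIControl-1 (0.537) or CIControl-2 (0.0682), and smooth muscle genes not without TIControl-1 (0.537) or CIControl-1 (0.126).

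The response at 20 dpc was tested as a difference between strains. edgeR called 1 feature, LOC110507825 (adjusted p = 3.66e-08), with 0 counts in commercial sham pools. The response of smooth muscle genes differed between strains by camera (0.0202, or 0.886 with an estimated correlation), with smtnb at 0.93 (0.804 by edgeR) and lmod1b at 0.78. So did that of matrix genes (0.0032, or 0.886 with an estimated correlation), with sparc at 1.00 ± 0.43 (0.804) and col5a2a at 0.89 ± 0.29 (0.804). Adjusted over the list alone 1 and 4 members passed. The difference comes from the commercial sham pools of 20 dpc, also part of the commercial infection and sham strain calls of these lists. Their mean log2 CPM was 7.92 for smooth muscle (other groups 6.99 to 7.24) and 9.54 for matrix genes (other groups 8.52 to 8.87), while infected and sham select pools had equal means (7.19 and 8.84). Smooth muscle genes did not pass without TI1-1 (0.0608), TIControl-1 (0.642) or CIControl-1 (0.281), and matrix genes not without TIControl-1 (0.305). The interferon list stood at 0.537. The tally was 2 without TI2-2, 6 without TIControl-1, 10 without TIControl-2, 6 without CIControl-1 and 6 without CIControl-2. DESeq2 called 54, tank sums 4, a fit of the compared groups only 3 and limma-voom 0.

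Over all 12 comparisons, 42 of 252 list tests passed camera. With an estimated correlation 4 did: antigen presentation and T and NK cell genes in commercial fish, and interferon and antigen presentation genes in select fish, all at 4 dpc.

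**Figure D4:**
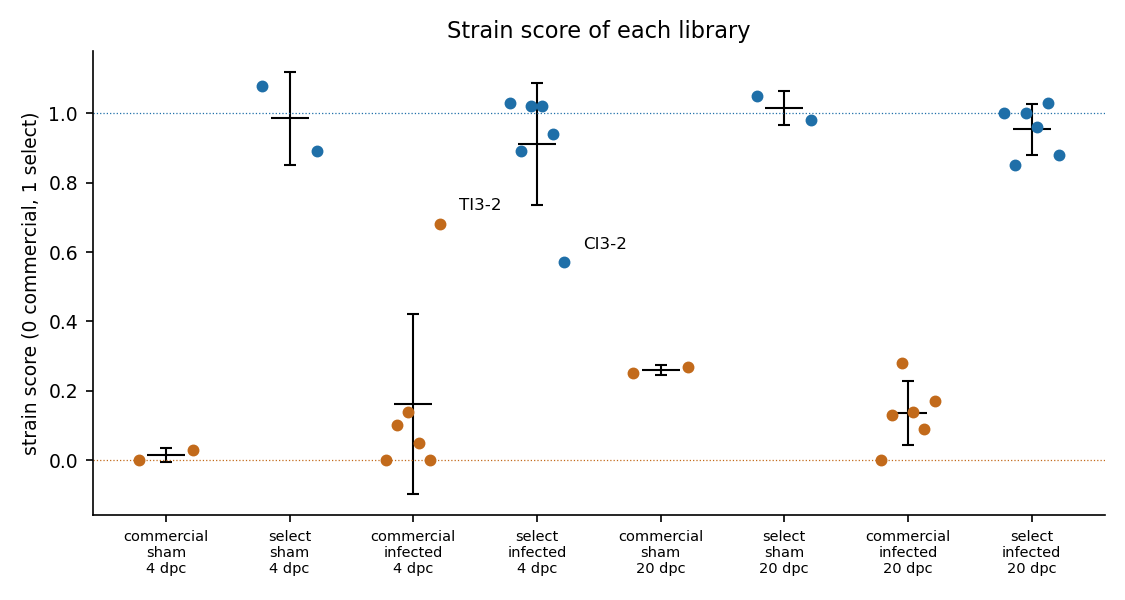
Strain score of each library, where 0 is the commercial and 1 the select mean over genes chosen on the other day. At 4 dpc the pools TI3-2 (0.68) and CI3-2 (0.57) lie between the strains.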

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

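Libraries stood apart from the other 5 of their group by Dixon's rule in 18 of 100 tests (25 measures in 4 infected groups), where chance gives about 1 in 20, or 5. All tests that weigh explanations for the 3 patterns in this part were chosen after seeing the results.

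The first pattern is a pair of pools between the strains at 4 dpc. On a strain score, with 0 for commercial and 1 for select, TI3-2 of the commercial strain stood at 0.68 (others of its group 0 to 0.14) and CI3-2 of the select strain at 0.57 (others 0.89 to 1.03). An exchange of the whole libraries would leave no marker of the own strain above the range of the other strain. TI3-2 kept 7 of 11 such markers and CI3-2 kept 11 of 16, which argues against it. The counts do not exclude it, as a held-out library can carry markers of the other strain, and dhrs7 went as an exchange would give. This gene was at 13.4 CPM in TI3-2 and 0 in CI3-2, against 0 in the 15 other commercial and 2.61 to 20.1 in the 15 other select libraries. Fish or RNA of both strains in the pool would fit for TI3-2, as 13 of 16 select markers lay above the commercial range, against at most 4 in any other commercial library. For CI3-2 it stays open beside variation between fish of a strain: 6 of 11 commercial markers lay above the select range, but the held-out select library CI1-2 of 20 dpc carried 14 of 21. The label of each pool was kept, and the strain comparison of 4 dpc is given with and without both pools in the report.

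The second pattern is a small interferon score at 4 dpc in TI3-2 (6.02, others 7.25 to 7.67) and in CI2-1 of the select strain (5.83, others 7.12 to 7.68). A smaller response of rising genes outside the interferon list would fit, with a median share of 0.45 and 0.43 of the response of the other pools, whose own shares were 0.91 to 1.2, while for falling genes it stays open, as 0.64 and 0.7 lay within the range of the others (0.49 to 1.16). A day score over 12 genes that differed between days in sham fish argues against an exchange of libraries between days. It was 0.28 in TI3-2 and 0.24 in CI2-1, against 0.74 to 1.11 in infected pools of 20 dpc. The score does not exclude an exchange, as its genes were chosen with both pools under their labels. Other infected pools of 4 dpc ran from −0.37 to 0.55. Strain mixture is excluded for CI2-1, whose strain score of 1.02 lay within the range of the other select libraries (0.85 to 1.08, without CI3-2). For TI3-2, itself between the strains, it stays open: CI3-2, also between the strains, had an interferon score of 7.68, but 1 library excludes nothing.

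The third pattern is LOC110507825, whose response to infection at 20 dpc differed between strains. It had 0 counts in both commercial sham pools of that day, against 4.99 to 18.1 CPM in the other 30 libraries, so the fitted log2 difference of −9.61 is no measured size, and the floor gives a commercial response of at least 33.2-fold. Reads assigned to another transcript would fit: an unmatched transcript neighbouring by RefSeq number averaged 10.9 CPM in these pools and 0.802 elsewhere. It has 4801 bases, against 4789 for the gene. It was the higher in these pools of 2 such transcripts, the other standing at 0 CPM there, and sequences were not compared. The sums of gene and neighbour in these pools (mean 10.9 CPM, lower 10.7) lay within the range elsewhere (8.41 to 18.1). Loss of expression of the gene in this tank stays open, as it was not tested whether the neighbour belongs to the same locus. No other biological explanation was tested.

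Other measures of TI3-2 apart from its group at 4 dpc were antigen presentation (6.05, others 6.97 to 7.49), inflammation (1.37, others 3.29 to 3.93), epithelial barrier (6.4, others 6.77 to 6.94), principal component 1 (2.7, others 77.5 to 118.5) and component 2 (16.3, others −43.2 to −33.8). CI2-1 also stood apart in inflammation (1.5, others 3.3 to 3.97). The select pool CI2-2 of 20 dpc stood apart in interferon (6.43, others 4.01 to 4.66), antigen presentation (5.98, others 5.23 to 5.49), proliferation (3.75, others 4.43 to 4.77), detoxification (5.13, others 5.69 to 5.88) and principal component 1 (34.3, others −56.8 to −34). In the commercial strain TI3-1 stood apart in goblet and enteroendocrine genes at 4 dpc (2.23, others 3.26 to 3.86) and in B cell genes at 20 dpc (2.54, others 1.55 to 1.81), and TI1-2 of 20 dpc in estimated reads (11330599, others 7623316 to 8395885). Responses at 20 dpc differed between strains by camera in smooth muscle (adjusted p = 0.0202) and extracellular matrix genes (0.0032), not with an estimated correlation (0.886 each) and not without TIControl-1 (0.642 and 0.305).

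Other ways to divide the same libraries into groups were tested too. For the infected strains at 4 dpc this count alone cannot exclude chance for the tally: 5 of 60 divisions called as many features as the real 53. The highest other, 841, points to a structure of the samples, as it exchanges TI3-2 and CI3-2. Of the 4 divisions as large beside the real one, the 841 included, 3 exchange TI3-2. In 1 of these, with 209 features, each side holds 3 pools of each strain, so which pools count as exchanged is arbitrary. The 6 higher and 7 lower features shared with the separate libraries of 20 dpc exceed the 0.0316 and 0.0397 given by chance for independent features. Features are not independent, and both days were sampled from the same tanks. At 20 dpc a chance division of pools is unlikely, with the real division (98) the only 1 as large of 60 (462 are possible) and 15 the highest other. Between days it is unlikely too for infected fish in both strains, each with the real division the only 1 of 60 as large (commercial 4681, highest other 1524, and select 3248, highest other 1851). These divisions were of single pools and not of tanks, so they cannot weigh differences between tanks. The tests of the days were chosen before, and those of the strains after, their results were seen.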

How the results depend on the processing

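Of 4035 alternative values of 208 named gene results, 3271 stayed on their side of the threshold, 738 were weaker, 26 stronger and 0 reversed. Weaker values numbered 453 of 2024 with libraries left out in turn, 94 with tank sums, 69 with a fit of the compared groups only, 34 without an expression filter, 33 with the replicate block, 27 with limma-voom, 15 with effective length offsets, 9 without both pools between the strains, 3 with DESeq2 and 1 with RLE scaling. The causes were not tested, except that tank sums and omissions have fewer samples. A group left with 1 sham pool is assumed to vary like the other groups. Depth limits genes near the floor of 0.265 to 0.45 CPM.

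Left out in turn, libraries gave these ranges. Infection at 4 dpc called 75 to 3387 features in the commercial and 63 to 2113 in the select strain, with 34 to 1288 shared, and at 20 dpc 1 to 19 and 8 to 87. Infected strains differed in 11 to 208 features at 4 dpc and 56 to 173 at 20 dpc, sham strains in 8 to 15 and 7 to 13, and responses in 0 to 15 and 1 to 10. Days differed in 3602 to 5298 features (commercial) and 2163 to 3792 (select). List tests passed 36 to 46 times.

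In the order infection 4 dpc commercial, select and shared, infection 20 dpc commercial and select, infected strains 4 and 20 dpc, sham strains 4 and 20 dpc, response differences 4 and 20 dpc, DESeq2 called 4386, 3155, 2058, 254, 1218, 368, 591, 98, 250, 52 and 54 features, and tank sums called 971, 392, 265, 4, 5, 0, 6, 3, 7, 2 and 4. Tank sums called 2666 and 1334 between days. The fit of the compared groups only called 618 and 176 for infection at 4 dpc with 112 shared, 2 and 89 at 20 dpc, 0 between infected strains at 4 dpc, 0 between sham strains and 3 for the response difference at 20 dpc, and 1398 between days in the select strain. limma-voom called 54 and 189 for infection at 20 dpc, 5 and 5 between sham strains, and 0 for the response difference at 20 dpc. At 4 dpc limma-voom split its infection calls into 1147 up and 1244 down (commercial) and 570 up and 727 down (select), against 1573 and 1026 and 995 and 597 by edgeR. The balance of infection calls in the select strain at 20 dpc turned from 5 up and 36 down to 768 and 450 by DESeq2. The cause was not tested.

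Without an expression filter 1027 features were called for infection in the select strain at 4 dpc, 682 shared, 11 for infection in the select strain at 20 dpc and 21 between infected strains at 4 dpc. Effective length offsets called 3 between sham strains at 20 dpc. Matched genes alone gave 3 for infection in the commercial strain at 20 dpc and 1 between sham strains at 4 dpc, and omission of both pools between the strains gave 454 between infected strains at 4 dpc. With an estimated correlation 4 list tests passed instead of 42. With older symbols 47 passed, and the erythrocyte list, then with 4 members including hba1 and hbb1, was lower after infection at 20 dpc in the commercial (median −0.95, 0.00136, or 0.233 with an estimated correlation) and the select strain (−1.13, 0.00229, or 0.525). Between infected strains at 20 dpc camera then also passed myeloid genes as higher in the select strain (median 0.57, 0.00957, or 0.4 with an estimated correlation). Enterocyte (−0.11, 0.0419, or 0.673) and adipose genes (−1.05, 0.0419, or 0.4) passed as lower. RLE scaling and a prior of 0.5 moved none of these counts by over 1.5 times.

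The replicate block, fitted here to the 12 infected libraries of a day or strain, called 0 features between infected strains at 4 dpc, 12 at 20 dpc and 556 between days in the select strain. The fit of the compared groups without the block called 0, 131 and 1398, so the fall to 0 cannot be put down to the block. The block changed no other count by over 1.5 times. The numbers do not pair the samples: correlations within a replicate number between strains were −0.207 to 0.0554 at 4 dpc and −0.0312 to 0.129 at 20 dpc, with 1 of 6 and 2 of 6 libraries correlating best with their own number. The correlation within tanks was −0.00376.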

Other observations

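Sham fish also differed between days. In the 4 sham pools of 20 dpc against the 4 of 4 dpc, a comparison chosen after seeing the data, the ER chaperone genes grp94 and calr3b were among those lower: grp94 by 1.44 ± 0.24 (log2, SE; adjusted p = 0.00272 by edgeR; 320 ± 71.8 against 864 ± 106 CPM, SD, n = 4 each), calr3b by 1.35 ± 0.21 (0.00251; 246 ± 34.3 against 625 ± 43.7 CPM). Also lower were calr (−1.30, 0.0247), calr3a (−1.17), dnajc3a (−1.31), creld2 (−1.20), sdf2l (−1.26), canx (−0.75) and the secretory genes ddost (−1.22) and ssr3 (−1.02). Single genes of lipid metabolism that were lower were tm7sf2 (−1.51, 0.0436), hsd17b7 (−1.25, 0.0161), acat2 (−1.26, 0.0426), acaca (−1.12, 0.0324), acadvl (−0.95 ± 0.19, 0.0096), hadhb (−0.83, 0.00951), cpt2 (−0.83), acaa2 (−0.83), etfdh (−0.60) and slc25a20 (−1). Higher were fkbp5 by 2.05 ± 0.36 (0.00443; 31.3 ± 7.6 against 7.47 ± 1.78 CPM), which stood at −0.77 between the same days in infected fish, and klf9 by 1.94 ± 0.54 (0.0449), each known to respond to glucocorticoids. Other higher genes were jak3 (0.91 ± 0.16, 0.00443), itgae.2 (0.83, 0.00502), pik3cd (0.82), cblb (2.02), cdkn1d (1.30) and bcl2l11 (1.16, 0.0146). These genes were picked from the called ones, and beyond the lists below no group of them was tested. Further falls were asns (−1.20), slc13a1 (−1.57), nucb2b (−1.68), rbp7b (−1.86), vil1 (−0.53) and mcm7 (−0.58).

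The list means in sham fish moved from 6.14 ± 0.16 to 5.19 ± 0.20 for sterol synthesis, from 6.30 ± 0.21 to 5.70 ± 0.13 for fatty acid oxidation and from 0.61 ± 0.19 to 1.12 ± 0.05 for T and NK cells (SD, n = 4 each). Camera passed fatty acid oxidation (5 of 10 fell, 6 when adjusted over the list alone; adjusted p = 1.86e-06, 0.168 with an estimated correlation) as lower. It also passed as lower sterol synthesis (0 of 9, 7 when adjusted over the list alone; 5.95e-06, 0.249 with an estimated correlation) and proliferation (1 of 7, 5 when adjusted over the list alone; 0.000506, 0.249 with an estimated correlation). Lower, too, were ER and heat stress (3 of 10 fell, 4 fell and 1 rose when adjusted over the list alone, median −0.2; 0.032, 0.313 with an estimated correlation), enterocyte (1 of 13; 0.0241, 0.313 with an estimated correlation) and detoxification genes (0.0355, 0.249 with an estimated correlation). T and NK cell genes (0.00247, 0.201 with an estimated correlation), smooth muscle and extracellular matrix genes (0.0241, 0.313 with an estimated correlation, each) and growth axis genes (0.0355, 0.249 with an estimated correlation) were higher. The day effect in sham fish differed from that in infected fish for interferon (2.38e-14, 0.133 with an estimated correlation), antigen presentation (2e-08, 0.095), sterol (1.6e-06, 0.133), fatty acid oxidation (0.000206, 0.133), T and NK cell (0.000206, 0.095), detoxification (0.00919, 0.133) and inflammation genes (0.00121, 0.207). In the sterol list the sham means of 4 dpc (6.27 commercial, 6.01 select) lay above, and those of 20 dpc (5.3 and 5.08) below, the infected means of the same days (5.45 and 5.47, then 5.81 and 5.90), so the falls at 4 dpc and rises at 20 dpc given for infection coincide with a day difference in the sham tanks. The falls in fatty acid oxidation genes given for infection at 4 dpc do so too, with infected means of 5.71 and 5.77 at 4 dpc and 5.69 and 5.71 at 20 dpc (commercial, then select). Proliferation (sham 5 and 5.17 at 4 dpc, 4.46 and 4.57 at 20 dpc, infected 4.49 and 4.42 at 4 dpc) and detoxification genes (sham 6.04 and 5.72, then 5.6 and 5.49, infected 5.5 and 5.46 at 4 dpc), given as lower with infection at 4 dpc, show the same. The rises of T and NK cell genes given for infection at 4 dpc also coincide in part with a day difference in sham fish. Their sham means were 0.62 and 0.6 at 4 dpc and 1.08 and 1.15 at 20 dpc (commercial, then select). Infected means of 4 dpc (1.75 and 1.52) lay above the sham means of both days. Some lists given for infection at 20 dpc also moved between 4 and 20 dpc in sham fish. In commercial fish these were enterocyte (sham 8.26 to 7.98, infected 8.11 to 8.21) and growth axis genes (sham 1.35 to 1.94, infected 1.47 to 1.57). Smooth muscle (sham 6.99 to 7.92, infected 7.15 to 7.24) and extracellular matrix genes (sham 8.52 to 9.54, infected 8.56 to 8.7) did so there too. In select fish they were ER and heat stress genes (sham 5.72 to 5.35, infected 6.01 to 5.78).

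edgeR called 1254 features between the sham days, 378 up and 876 down (6878 at unadjusted p below 0.05). Of the 1254, 313 were also called with the same sign between days in infected fish and 103 with the opposite sign. The tally was 90, 838, 139 and 194 without TIControl-1, TIControl-2, CIControl-1 or CIControl-2 of 20 dpc, and 148, 543, 82 and 1405 without the same pools of 4 dpc. A chance division of pools is unlikely by a test chosen after seeing the result. Over 35 divisions of the 8 sham libraries, only 1, the real one (979 in a fit of these libraries), was as large, and the highest other called 40. The test treats pools as independent, although they come from 1 tank per strain. Fish age and sampling day are not separable in this comparison, whereas the same sham tank of each strain was sampled on both days.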
